A study of Homo sapiens with 6 samples.

How the data were processed

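The series holds 6 RNA sequencing libraries of HEK293 cells, 3 after transfection with an empty plasmid and 3 after transfection with a plasmid that carries pri-mir-124. Per the labels' protocols, polyadenylated RNA was isolated and sequenced as read pairs on an Illumina instrument. The authors deposited 1 table of raw counts per library, with 63677 Ensembl gene IDs and 5 closing lines that name no gene. Per the submitters' processing notes, the build was hg19 and the tools were TopHat2, an aligner, and HTSeq, a counter. Versions, the annotation and the strand setting are not given in the sources used here. The 5 lines that name no gene were kept out of library sizes and tests. Reads in no annotated gene made up 6.39 ± 0.0667% of counted reads with the empty plasmid and 6.96 ± 0.841% with the pri-mir-124 plasmid (SD, n = 3), and reads that matched more than 1 gene 7.61 ± 0.0167% and 7.50 ± 0.0600%. Without a stated strand setting, reads of overlapping genes on opposite strands may not be separable, and multi-copy families can lose or share reads.

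Groups and replicate numbers were taken from the labels. No pair of libraries in a group agreed within sampling noise: the chi-square of counts over its degrees of freedom was 3.02 to 3.73 among empty plasmid libraries and 4.75 to 11.2 among pri-mir-124 plasmid libraries, over genes with a summed count of 20 or more. All 6 were therefore counted as separate samples. Gene symbols came from the GENCODE 29 annotation of GRCh38 and the gene table given with it, which matched 52526 IDs (82.5%), among them 17796 of the 19805 tested. Coordinates in the text are GRCh38 and were not converted to the authors' build.

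Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes scaled by TMM, dispersions estimated, and groups compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values use the total of counts over tested genes times the TMM factor of the library. Depth was 31018325 to 37196402 gene counts per library, and 3 counts are worth 0.0813 to 0.0961 CPM on that scale. The floor for a gene at 0 was 3 counts per library. Floors and 95% intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

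The 3' UTR of each gene was the longest among its complete protein-coding transcripts, available for 19066 genes and for 13834 of those tested. It was searched for the miR-124-3p 8mer GTGCCTTA, the 7mer-m8 GTGCCTT, the 7mer-A1 TGCCTTA and the 6mer TGCCTT. A site in the text is a 7mer or 8mer unless a 6mer is named. Genes without an annotated 3' UTR counted as not searched. Genes with a site were compared with genes lacking a 6mer by limma 3.58.1 camera with a preset correlation of 0.01 on log-CPM with a prior count of 2, and lower genes were tested for sites by a two-sided Fisher's exact test. Each 7-base word present in at least 100 genes and absent from at least 100 was ranked by linear regression of log2 fold change on its presence and log UTR length. Genes are not independent replicates in these tests.

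Before the data were examined, 20 gene lists were fixed: miR-124 targets from the literature, neuronal genes, the REST corepressor complex, splicing regulators, the microRNA pathway, interferon response, p53 response, cell cycle, unfolded protein response, heat shock, cholesterol synthesis, glycolysis and hypoxia, adhesion and matrix, immediate early genes, ribosomal proteins, mitochondrially encoded transcripts, replication-dependent histones, and markers of fibroblasts, leukocytes and epithelial carcinoma lines. They were tested with camera, with camera using an estimated correlation, and with fry. Camera called 12 of the 20 (5 up, 7 down) and fry 14. With an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05. A further 7 lists were chosen after seeing the data: antigen presentation, interferon genes and receptors, nucleic acid sensing, NF-kB targets, the apolipoprotein L family, nuclear oxidative phosphorylation genes and mitochondrial RNA handling. Their tests were adjusted over those 7 lists alone.

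Named genes followed a rule also fixed before: every gene whose symbol starts with MIR124, then the 12 protein-coding genes with the largest log2 fold change in each direction with adjusted p under 0.05, a mean of 5 CPM or more and no overlap between groups, then up to 4 members of each list with the smallest p, and PTBP1, PTBP2 and CTDSP1 in any case. Groups did not overlap for 6145 genes (31.0%), where chance gives 10%. Genes named outside the rule are said to be so. The values of 1 gene chosen by the rule are not reported here.

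Alternatives fixed beforehand were RLE size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, stricter thresholds, an estimated correlation, other definitions of the 3' UTR and site, and a background matched on UTR length. Those added after seeing the data were robust empirical Bayes, scaling to genes without a site, omission of the interferon list, logistic regression on sites with UTR length and expression, and the 8mer set with an estimated correlation. On counts simulated from these libraries, with 200 genes changed before the filter and 19498 genes tested after it, edgeR recovered 36.7% of 49, 54.3% of 46, 84.0% of 50 and 100% of 46 tested genes changed by 0.25, 0.5, 1 and 3 on the log2 scale, and 3 of its 134 calls were false. A simulated shift of -0.1 in a set of genes with a site was returned as -0.103 with the seed ranked first. No shift was returned as 0.005 (p = 0.753 in camera with its preset correlation) with the seed at rank 12829. These simulated tests covered 9081 and 9071 genes, fewer than the 3471 with a site and 6911 with no match in the data. They therefore did not check the site test on the gene set used, nor its preset correlation on these data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and plots.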

Results

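Gene expression was measured by sequencing of polyadenylated RNA in HEK293 cells, a human embryonic kidney line that takes up plasmid DNA readily. One group of 3 libraries came from cells given a plasmid that carries pri-mir-124, the primary transcript from which the microRNA miR-124 is cut. The other group of 3 came from cells given the empty plasmid. Each well received 2 µg of plasmid with 5 µL of a lipid reagent, the medium was replaced after 6 hours, and RNA was taken 48 hours after transfection. The libraries held 32031481, 32975695 and 37196402 gene counts with the empty plasmid and 33260875, 31018325 and 33580525 with the pri-mir-124 plasmid. At these depths 3 counts were worth 0.0813 to 0.0961 CPM, the unit of counts scaled to each library's total over tested genes times its TMM factor. Log-CPM profiles correlated at 0.991 to 0.993 within groups and 0.983 to 0.984 between them, and the first principal component, with 53.3% of the variance, separated the groups. The labels speak of triplicates and do not say that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical.

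The hairpin carried by the plasmid was read first, as a check of the labels. MIR124-2 (ENSG00000207816), a microRNA gene of 109 bp on chromosome 8 from 64379149 to 64379257 (GRCh38), lies within the span of the long non-coding RNA gene MIR124-2HG. It had 0 counts in every empty plasmid library and 2936, 2783 and 2899 counts in the 3 pri-mir-124 plasmid libraries. Its level of 87.4 ± 1.84 CPM (SD, n = 3) was at least 978-fold higher than the floor of 3 counts per library. MIR124-3, a hairpin of the same microRNA on chromosome 20 from 63178500 to 63178586, and the host gene MIR124-2HG had 0 counts in all 6 libraries, which allows up to 0.0961 CPM. MIR1245A also had 0 counts in all 6, and MIR1249 had 0 to 15. The third hairpin gene, MIR124-1, was not analysed here.

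The comparison asked which transcripts change when pri-mir-124 is expressed. Genes of the antiviral interferon response rose, with a median log2 fold change of 4.50 over 30 genes, the largest among the 20 fixed lists. Genes whose 3' untranslated region (3' UTR) holds a 7mer or 8mer match to the miR-124 seed made up 44.6% of the 1149 lower genes with a searched 3' UTR, against 23.3% of the other genes searched. ITGB1, LAMC1, IQGAP1 and CTDSP1 were among them, and most lower genes changed by less than 2-fold. Most mitochondrially encoded mRNAs fell, while the mitochondrial small ribosomal RNA rose. Of 19805 genes tested, 1400 were higher and 1436 lower with the pri-mir-124 plasmid at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The higher genes had the wider range: 314 of them differed by more than 2-fold and 86 by more than 8-fold, against 15 lower genes beyond 2-fold. The median log2 fold change was 0.35 among higher genes and -0.22 among lower genes. Leaving out 1 library brought the counts to 885 higher and 841 lower without empty plasmid replicate 1, to 892 and 901 without empty plasmid replicate 3, and to 925 and 897 without pri-mir-124 plasmid replicate 3.

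**Figure D1:**
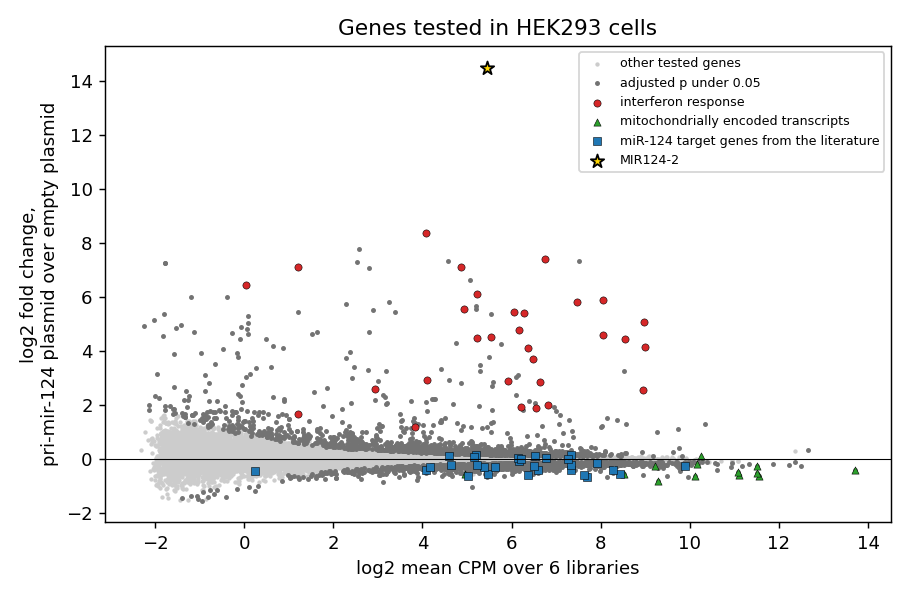
Log2 fold change of every tested gene, pri-mir-124 plasmid minus empty plasmid, against log2 of its mean CPM over the 6 libraries, with dark points for genes past an adjusted p of 0.05 in edgeR's test and coloured marks for 3 fixed lists and MIR124-2. The 30 interferon response genes lie above 1, and of the 1436 lower genes 15 lie beyond 2-fold, while the height of MIR124-2 depends on the prior count because it had 0 counts with the empty plasmid.

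All 30 fixed interferon response genes rose, and 30 did so when adjusted over the list alone. IFIT2 and IFIT3 rose by 5.80 ± 0.09 (SE, edgeR adjusted p = 3.76e-18) and 5.90 ± 0.11 on the log2 scale without a site. IFIT2 went from 6.33 ± 1.54 to 350.4 ± 25.0 CPM (SD, n = 3). IFITM1, a membrane protein that hinders virus entry, rose by 4.78 ± 0.08 without a site. DDX58, the cytoplasmic RNA sensor RIG-I, rose from 12.9 to 165 CPM and has no site. IFNB1, the interferon beta gene, stood at 0.0196 CPM with the empty plasmid and 2.04 CPM with the pri-mir-124 plasmid, also without a site; it was named after its value was seen. The list took 0.0508 ± 0.00522% of gene counts with the empty plasmid and 0.709 ± 0.0201% with the pri-mir-124 plasmid (SD, n = 3), 13.9-fold more. The set test camera gave the list an adjusted p of 1.52e-48 with its preset correlation and an adjusted p = 0.0524 with an estimated correlation.

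Of the 12 protein-coding genes with the largest rises under the naming rule, 6 belong to the fixed interferon list. RSAD2, which makes an antiviral nucleotide, rose from 2.29 ± 0.840 to 364 ± 22.0 CPM, a log2 fold change of 7.34 ± 0.11 (edgeR adjusted p = 1.56e-18, 6mer only). OAS2, an enzyme that activates RNA decay on sensing double-stranded RNA, rose by 7.41 ± 0.13 with a 6mer only, and MX2 by 7.11 ± 0.20 and IFI44 by 6.12 ± 0.14 with no site. APOL6 rose by 7.34 ± 0.17 and TRIM22 by 6.63 ± 0.14, both with a 7mer-A1 site. Levels with the empty plasmid were close to the floor for XAF1 (0.0981 CPM, 7mer-A1 site), APOL1 (0.0490, 6mer), GBP1 (0.0715, no site) and SLC15A3 (0.0934, no site). With the pri-mir-124 plasmid those 4 genes reached 33.9 ± 1.96, 11.8 ± 2.36, 11.5 ± 1.43 and 13.7 ± 0.964 CPM (SD, n = 3). In all, 3 of the 12 held a 7mer or 8mer site.

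The 12 largest falls under the same rule were 10 nuclear genes and 2 mitochondrial ones, and all 10 nuclear genes held a miR-124-3p site in the 3' UTR. TNFRSF10D, a decoy receptor for the death ligand TRAIL (chromosome 8, 23135588 to 23164030), fell from 46.5 ± 0.771 to 22.5 ± 1.28 CPM, a log2 fold change of -1.05 ± 0.06 (edgeR adjusted p = 1.87e-10, 7mer-A1 site). ITGB1, the integrin beta 1 chain (chromosome 10, 32900319 to 33005792), fell from 254 ± 6.09 to 161 ± 4.12 CPM, or -0.66 ± 0.04, with 2 sites in a 3' UTR of 1323 bases. COL4A1, a basement membrane collagen, and B4GALT1, a galactosyltransferase, each fell by 0.64 on the log2 scale and carry 8mer sites. SLC16A13 (-0.79) and CREB3L2 (-0.62) fell with an 8mer site, and SUMF1 (-0.86), TMEM168 (-0.63) and RRAS (-0.62) with a 7mer-m8 site. FAM172A fell by 0.64 with a 7mer-A1 site.

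Of 30 miR-124 targets taken from the literature, 19 fell and 1 rose. Adjusted over the list alone, 19 fell and 3 rose. The median log2 fold change was -0.28, and camera gave an adjusted p of 2.38e-08, against an adjusted p = 0.0524 with an estimated correlation. IQGAP1, a scaffold of the actin cytoskeleton, fell from 238 ± 2.84 to 156 ± 3.18 CPM (8mer site), and LAMC1, the laminin gamma 1 chain, from 413 ± 5.44 to 282 ± 6.21 CPM (4 sites, 7mer-m8). CD164, a sialomucin, fell by 0.42 ± 0.03 on the log2 scale with an 8mer site. STAT3 was the member that rose, by 0.16, although its 3' UTR holds an 8mer site. It was named after its value was seen. In this list 28 of the 30 members carry a site.

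**Figure D2:**
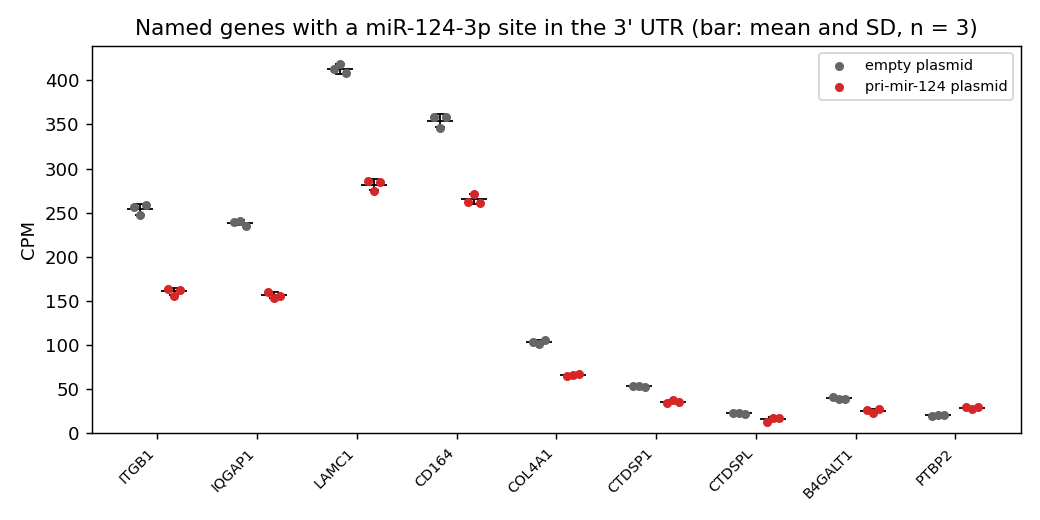
CPM in each library for 9 named genes with a miR-124-3p site in the 3' UTR, with the empty plasmid and the pri-mir-124 plasmid side by side, and bars for mean and SD (n = 3). ITGB1, IQGAP1, LAMC1, CD164, COL4A1, CTDSP1, CTDSPL and B4GALT1 are lower in all 3 pri-mir-124 plasmid libraries, and PTBP2 is higher in all 3.

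Across all genes, the fall followed the strength of the seed match. Among 6911 genes with no match in the 3' UTR, 6.27% were lower, against 8.68% of 1233 genes with a 7mer-A1 site (TGCCTTA), 15.1% of 1774 with a 7mer-m8 site (GTGCCTT) and 29.7% of 464 with an 8mer site (GTGCCTTA). A 6mer alone gave 5.88% of 3452 genes. The median log2 fold change of 8mer genes lay 0.106 ± 0.0311 (SD, n = 3) below that of genes with no match, as a mean over the pri-mir-124 plasmid libraries. Of the 1149 lower genes with a searched 3' UTR, 513 (44.6%) held a 7mer or 8mer site, against 2958 of 12685 others (23.3%), an odds ratio of 2.65 (95% interval 2.34 to 3.01; two-sided Fisher's exact test, p = 1.57e-51). Among 1148 higher genes 19.8% held a site, against 25.6% of the other genes searched, an odds ratio of 0.717 (p = 1.02e-05, the same exact test). Those others include the lower genes, which are rich in sites and so widen the difference. UTR length was not held equal in this comparison. GTGCCTT ranked first for lower expression of all 16027 7-base words tested in 3' UTRs (z = -7.78), with TGCCTTA next, while the 7-base word of the opposite strand's product, miR-124-5p, ranked 9768. All 3471 genes with a 7mer or 8mer site had a median only -0.039 from genes with no match, where camera gave p = 0.00218 with its preset correlation and p = 0.0784 with an estimated correlation.

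**Figure D3:**
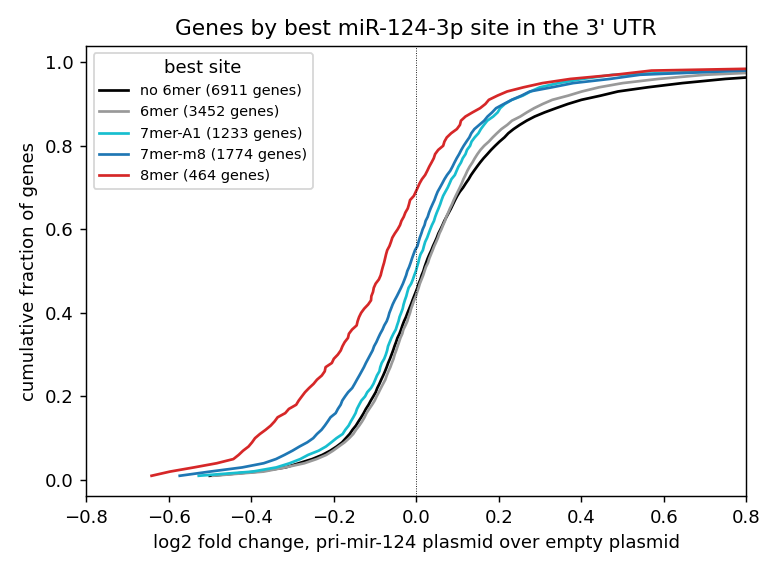
Cumulative fraction of genes (vertical axis) at or below each log2 fold change, pri-mir-124 plasmid over empty plasmid (horizontal axis), with 1 line per strongest miR-124-3p match in the 3' UTR. The line of the 464 genes with an 8mer site lies furthest towards lower expression, and that of the 3452 with a 6mer alone lies close to that of the 6911 with no match, parting from it among higher genes.

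PTBP1, a splicing repressor that holds back neuronal exons, fell from 1044 ± 30.0 to 859 ± 36.0 CPM (SD, n = 3), a log2 fold change of -0.28 ± 0.04 (edgeR adjusted p = 2.28e-05). Its 3' UTR of 1501 bases (gene on chromosome 19, 797075 to 812327) holds 3 sites including an 8mer. PTBP2, its neuronal paralog, also has 3 sites including an 8mer, but in a searched 3' UTR of 10333 bases, the longest annotated. Which 3' UTR these cells use was not tested. PTBP2 rose by 0.53 ± 0.06 (edgeR adjusted p = 1.05e-05), from a range of 19.4 to 20.6 CPM over the empty plasmid libraries to one of 27.9 to 29.6 CPM. PTBP3 (-0.38) and QKI (-0.28), both with an 8mer site, fell too. Of 23 splicing regulators, 2 rose and 4 fell, and 2 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.136). The other riser was SRSF7 (0.12, no site) and the other that fell was HNRNPA1 (-0.18, 6mer), both named after their values were seen. Related sequences in PTBP1, PTBP2 and PTBP3 leave some uncertainty in how reads were shared.

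CTDSP1, a phosphatase recruited by the neuronal repressor REST, fell from 53.2 ± 0.535 to 35.8 ± 1.54 CPM, by 0.57 on the log2 scale, with 5 sites. Its relatives CTDSPL (-0.50, 3 sites) and CTDSP2 (-0.25, 2 sites) fell as well, as did the histone deacetylase HDAC1 (-0.20, no site). Of 14 genes of the REST corepressor complex, 4 rose and 4 fell, or 5 and 6 adjusted over the list alone, with a median log2 fold change of -0.04. Camera gave an adjusted p of 0.420, while limma's fry, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.0258. The 4 that rose, named after their values were seen, were SIN3A (0.18), RCOR3 (0.30), PHF21A (0.22), all with no site, and REST itself (0.22, 6mer).

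Among 20 neuronal genes 4 rose, and 5 rose adjusted over the list alone. Besides PTBP2 these were KIF5C, a neuronal kinesin (0.50 ± 0.06, no site), MAP2, a dendritic microtubule protein (0.61 ± 0.09, 6mer), and DPF1, a neuronal chromatin subunit (0.35 ± 0.07, no site). The list's median was 0.37 (camera adjusted p = 7.31e-05, and adjusted p = 0.0525 with an estimated correlation). Of 17 genes of the microRNA pathway, 2 rose and 1 did so adjusted over the list alone (camera adjusted p = 0.186). DGCR8, the partner of the hairpin-cutting enzyme DROSHA, rose by 0.19 ± 0.05 (6mer), and TNRC6C, a silencing cofactor, by 0.17 ± 0.06 (no site). Both calls were weak: over 14 alternatives edgeR's, DESeq2's or limma's adjusted p ran from 0.00242 to 0.0609 for DGCR8, which was lost without empty plasmid replicate 1 or pri-mir-124 plasmid replicate 3, and from 0.0322 to 0.170 for TNRC6C, which was lost in 10 of the 14, among them leaving out any empty plasmid replicate or pri-mir-124 plasmid replicate 1 or 2.

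Of 24 adhesion and matrix genes 11 fell and 1 rose, or 12 and 3 adjusted over the list alone, and 4 of the 11 that fell carry a site. Besides ITGB1, LAMC1 and COL4A1, the integrin linker TLN1 fell by 0.44 ± 0.04 with a 7mer-m8 site, and the riser was fibronectin, FN1 (0.16, no site), named after its value was seen. The median was -0.12 (camera adjusted p = 1.27e-04, and adjusted p = 0.0525 with an estimated correlation).

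In the p53 response 10 of 20 genes rose and 2 fell, or 13 and 2 adjusted over the list alone. GDF15, a secreted stress factor, rose from 4.69 ± 0.142 to 11.5 ± 1.25 CPM with no site. FAS, a death receptor, rose by 0.51 (6mer), DDB2 by 0.38 and GADD45A by 0.31, both without a site. The list's camera adjusted p was 1.05e-04, and the adjusted p = 0.141 with an estimated correlation. Of 20 unfolded protein response genes 6 rose and 2 fell, the same counts as adjusted over the list alone, with PPP1R15A, which restores translation after stress, up by 0.88 ± 0.05 and DDIT3 by 0.52 (neither with a site) and SDF2L1 down by 0.32 (7mer-m8). The camera adjusted p was 0.308. Of 22 immediate early genes 8 rose and 3 fell, or 10 and 4 adjusted over the list alone, led by ATF3 (0.44, no site), EGR1 (0.79, 7mer-m8), JUNB (0.32) and IER2 (0.30), the last pair with no site (camera adjusted p = 0.00426, and adjusted p = 0.160 with an estimated correlation). Among 14 heat shock genes the co-chaperone DNAJA1 rose (0.39 ± 0.03, no site) and 5 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.229). HSPB1 (-0.30) and HSPD1 (-0.16) were among those that fell, without a site, as was HSPA1B (-0.15), uncertain because the counting could split its reads with the near-identical HSPA1A.

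In the cell cycle list 7 of 31 genes fell and 1 rose, or 9 and 1 adjusted over the list alone. The mitotic genes CDC20 (-0.27, no site), AURKA (-0.31, 8mer), PLK1 (-0.22, no site) and CCNB1 (-0.15, no site) fell, and the replication licensing factor CDC6, named after its value was seen, rose by 0.14 with no site. Camera gave an adjusted p of 0.00230, and the adjusted p = 0.187 with an estimated correlation. Of 21 cholesterol synthesis genes 10 fell, and 15 adjusted over the list alone. INSIG1, a sterol sensor, fell by 0.36 ± 0.04 (6mer), HMGCS1 by 0.20 and MSMO1 by 0.29 (no site), and DHCR7 by 0.22 (6mer). The camera adjusted p was 2.17e-07, and the adjusted p = 0.141 with an estimated correlation. Of 24 glycolysis and hypoxia genes 10 fell, or 12 with 1 rise adjusted over the list alone, including LDHA (-0.23) and ENO1 (-0.19), both with no site, and NDRG1 (-0.38) and PGK1 (-0.24), both with a 6mer only (camera adjusted p = 6.25e-05, and adjusted p = 0.187 with an estimated correlation).

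Mitochondrially encoded mRNAs fell in 12 of 13 cases, by a median of -0.52. Adjusted over the list alone, 12 fell and MT-ND1 rose. They have no searched 3' UTR. MT-CO3, a subunit of cytochrome c oxidase, fell from 3636 ± 68.6 to 2374 ± 82.3 CPM (edgeR adjusted p = 6.14e-11), MT-CYB by 0.65 ± 0.04, MT-ND4L by 0.54 ± 0.04, and MT-ND6, read from the other strand, by 0.80 ± 0.06. MT-ND1, named after its value was seen, did not pass over all genes, with a log2 fold change of 0.09 ± 0.03 (edgeR adjusted p = 0.0615). Camera gave the list an adjusted p of 2.32e-10, and the adjusted p = 0.141 with an estimated correlation. Mitochondrial transcripts took 4.25 ± 0.160% of gene counts with the empty plasmid and 3.63 ± 0.0427% with the pri-mir-124 plasmid (SD, n = 3). MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4. Reads in the overlaps may have been set aside as matching more than 1 gene, so these genes are uncertain singly.

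**Figure D4:**
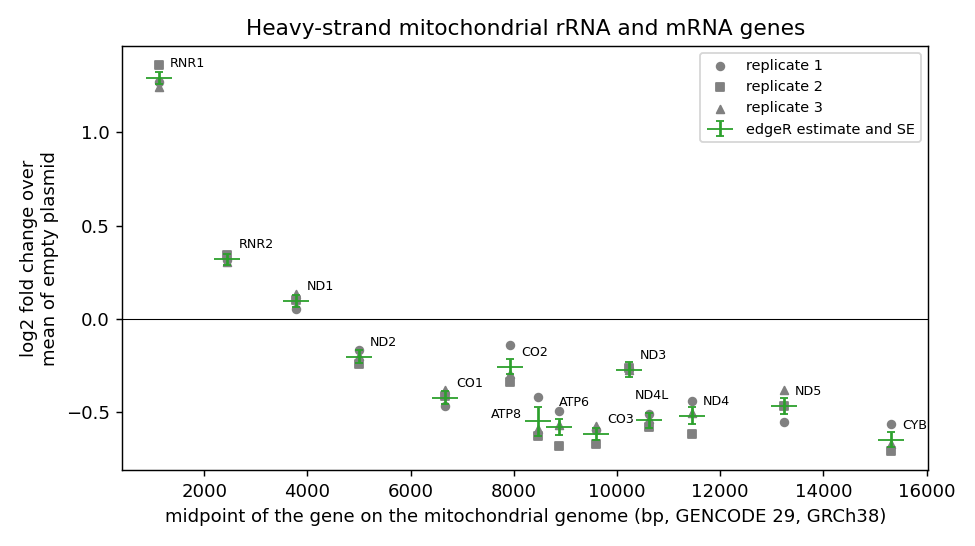
Log2 fold change, pri-mir-124 plasmid minus empty plasmid, of heavy-strand mitochondrial genes against the midpoint of each gene on the mitochondrial genome in bases (GRCh38), with 1 grey point per pri-mir-124 plasmid library and edgeR's estimate with its SE in green. MT-RNR1, named after its value was seen, rose by 1.29 and MT-CYB fell by 0.65.

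Ribosomal protein genes fell in 24 of 41 cases, and in 33 adjusted over the list alone, by a median of -0.14. RPL23 fell from 964 ± 30.0 to 756 ± 36.3 CPM (no site), RPL4 by 0.33 (6mer), RPL6 by 0.24 (no site) and RPS3 by 0.20 (8mer). Processed pseudogenes of this family make single members uncertain. Camera gave an adjusted p of 9.13e-12, and the adjusted p = 0.187 with an estimated correlation. Replication-dependent histone genes, whose mRNAs mostly end in a stem-loop in place of a poly(A) tail, rose in 7 of 11 cases, and in 9 adjusted over the list alone, by a median of 0.89. HIST1H2AC went from 5.13 ± 0.344 to 11.8 ± 0.537 CPM and HIST1H4H from 3.07 ± 0.698 to 7.20 ± 0.507 CPM, both with no site. HIST1H1C and HIST1H2BK, whose 3' UTRs were not searched, rose by 0.62 and 0.55. The camera adjusted p was 1.13e-06, and the adjusted p = 0.0525 with an estimated correlation. Histone genes are near-identical copies, so single members are uncertain.

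Of 4 leukocyte markers tested, CORO1A rose, from 2.38 to 3.60 CPM with no site (edgeR adjusted p = 0.0251, 0.0139 to 0.103 over 14 alternatives of which 5 ended the call: DESeq2 and leaving out empty plasmid replicate 1 or 2 or pri-mir-124 plasmid replicate 1 or 3). Adjusted over the list alone, 2 rose and 1 fell. The list's median was 0.38, with a camera adjusted p of 0.308, while fry gave an adjusted p of 0.0424. Of 6 fibroblast markers TWIST1 (-0.25, no site) and MMP2 (-0.45, 7mer-m8) fell, and 2 fell adjusted over the list alone. The list's median was 0.07 and its mean 0.08, while camera pointed down (adjusted p = 0.686). The TWIST1 call ended without empty plasmid replicate 1 (adjusted p = 0.0832, 0.00112 to 0.0832 over 14 alternatives in edgeR, DESeq2 or limma), and the MMP2 call in 9 of 14, among them leaving out any empty plasmid replicate or pri-mir-124 plasmid replicate 1 or 3, with a range of 0.0149 to 0.163. Among 7 markers of epithelial carcinoma lines edgeR's test called 0, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Their median was -0.03, their mean 0.03, and camera pointed down with an adjusted p of 0.686.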

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

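The values in this part were set beside the empty plasmid libraries without a test. Reads in no annotated gene, which no comparison used, made up 7.82% of counted reads in pri-mir-124 plasmid replicate 1 (95% Wilson interval 7.82 to 7.83%) and 6.92% in replicate 3 (6.91 to 6.92%). Both lie above the highest empty plasmid library, at 6.45% (6.45 to 6.46%), while pri-mir-124 plasmid replicate 2, at 6.14%, lies below the lowest, at 6.32%. The same 3 libraries differ most from each other in their counts, and the second principal component, with 12.8% of the variance, separates replicate 1 from replicate 2 of the pri-mir-124 plasmid.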

How the results depend on the processing

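The settings with robust empirical Bayes, scaling to genes without a site, omission of the interferon list, logistic regression and the 8mer set with an estimated correlation were chosen after seeing the data, the others before. An adjusted p under 0.01 left 713 higher and 717 lower genes, and a log2 fold change of at least 1 left 314 and 15, in each case because the threshold is stricter. Leaving out 1 library gave 885 to 1517 higher and 841 to 1727 lower genes. The lowest counts came without empty plasmid replicate 1 (885 and 841), empty plasmid replicate 3 (892 and 901) or pri-mir-124 plasmid replicate 3 (925 and 897), with fewer samples in each fit. RLE size factors gave 1352 and 1556, no filter 1379 and 1788, the 1 CPM filter 1489 and 1401, DESeq2 1048 and 1510, limma-voom 1365 and 1470, robust empirical Bayes 1462 and 1541, and scaling to genes without a site 1225 and 1821. DESeq2 kept 74.8% of the higher and 94.3% of the lower calls. The replicate number as a block gave 1483 and 1494. Same-numbered libraries did not deviate together (r = 0.005, -0.005 and -0.003), so no effect of pairing by number was seen. Whether the numbers pair the samples is not said in the labels. The shift of genes with a site, -0.039, ran from -0.053 to -0.029 with 1 library left out and stayed past its threshold there. With an estimated correlation, which widens the test, it was still -0.039 with p = 0.0784. Sites in coding sequence gave -0.000551 (p = 0.822 with the preset correlation), and the cause was not tested. The 8mer set gave -0.101 (p = 3.67e-10, and p = 0.0189 with an estimated correlation), and a background matched on UTR length -0.051 (p = 9.28e-05). The odds ratio of sites among lower genes ran from 2.02 to 3.38 with 1 library left out and was 3.59 in the logistic regression. The seed ranked 1 in every setting run. Camera called 12 lists with each library left out and 0 with an estimated correlation, where the smallest adjusted p was 0.0524, 6 lists had an unadjusted p under 0.05 and fry called 14. Over lists and settings 207 of 220 results kept direction and side of the threshold, 12 lost the call, all with an estimated correlation, and 1 gained it, splicing regulators with no filter. Over named genes 1312 of 1341 kept both, 27 lost the call and 2 gained it. MIR124-2 rose in every setting run. Depth sets the floor, where 3 counts are worth 0.0813 to 0.0961 CPM. At this depth, with 3 libraries per group, edgeR recovered 36.7% of simulated changes of 0.25 on the log2 scale, and neither was varied alone.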

Other observations

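The gene lists and the tests in this part were chosen after the results were seen, except the tests of genes that restrain interferon signalling and of RNA without a poly(A) tail, for which the outcome each explanation needs was written before. List tests here were adjusted over the later lists alone, so their adjusted values cannot be compared with those of the fixed lists. Before adjustment, the fixed interferon response list ranked ahead of antigen presentation and behind nucleic acid sensing in camera with an estimated correlation. Of 21 antigen presentation genes 17 rose, by a median of 1.02 on the log2 scale (camera adjusted p = 0.0174 with an estimated correlation). B2M, the light chain of MHC class I, went from 222 to 540 CPM and HLA-B from 33.6 to 119 CPM, and the peptide transporter TAP1 from 6.89 to 31.8 CPM. NLRC5, a transactivator of class I genes, rose by 2.82. TAP1 holds a 6mer and the others no site. HLA genes share reads, so single members are uncertain. The 3 tested apolipoprotein L genes rose, APOL2 by 1.82 with no site, in a family picked because APOL1 and APOL6 were among the 12 largest rises, so a set test of it carries no information.

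Of 15 nucleic acid sensing genes 9 rose and 1 fell (camera adjusted p = 0.0174 with an estimated correlation). DHX58 went from 0.464 to 20.6 CPM and TLR3 from 1.02 to 6.25 CPM, both with no site, and the RNA-editing enzyme ADAR from 411 to 820 CPM with a 6mer. The gene that fell was MAVS, the mitochondrial adaptor of RNA sensors, from 126 to 105 CPM, with a 7mer-m8 site. Of 12 interferon genes and receptors 4 rose (camera adjusted p = 0.0815 with an estimated correlation): IFNB1, IFNL1, IFNL2 and IFNL3 stood at 0.101 CPM or less with the empty plasmid and at 2.04, 4.51, 2.08 and 2.05 CPM with the pri-mir-124 plasmid, all with no site. IFNL2 and IFNL3 are near-identical and uncertain singly. Of 13 NF-kB targets 5 rose (camera adjusted p = 0.0477 with an estimated correlation), among them CCL5 from 0.220 to 5.48 CPM (6mer). The median over the 13 was 0.22. CXCL1, IL6, TNF, ICAM1 and CCL20, also on that list, had too few counts to be tested. ICAM1 had 13, 5 and 7 counts with the empty plasmid and 10, 6 and 7 with the pri-mir-124 plasmid. Of 33 nuclear oxidative phosphorylation genes 6 fell (adjusted p = 0.247 with an estimated correlation, camera), COX7C most, by 0.19 with no site. Of 20 genes of mitochondrial RNA handling 2 rose (adjusted p = 0.311 with an estimated correlation, camera): PNPT1, an exoribonuclease, from 84.9 to 229 CPM (6mer), and its partner helicase SUPV3L1 from 48.4 to 56.5 CPM (no site).

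For the rise of interferon genes, leukocytes in the cultures are argued against, since PTPRC, CD3D, CD3E, CD68, LYZ, TYROBP and HLA-DRA together had at most 2 counts in any pri-mir-124 plasmid library and up to 4 with the empty plasmid. These 7 of the 14 fixed leukocyte markers were picked after the data were seen, and 6 others, the ones reported here, did not move one way: CSF1R had 9, 2 and 7 counts with the empty plasmid and 26, 5 and 12 with the pri-mir-124 plasmid, SPI1 had 7, 17 and 13 against 8, 8 and 5, CORO1A rose from 2.38 to 3.60 CPM, and CD14 (0.641 and 1.16 CPM), CD74 (0.676 and 0.764) and LCP1 (147.4 and 137.1) did not pass the test over all genes, although adjusted over the list alone CD14 was higher and LCP1 lower. Loss of genes that restrain interferon signalling or nucleic acid sensing stays open: of 7 tested with a site 2 fell, which meets the outcome written before (at least 1), but a check added after the result showed that 1.03 would be expected from the 14.8% of all genes with a site that fell (one-sided exact binomial p = 0.277). Both that fell, NLRX1 (-0.37) and RNF125 (-0.31), restrain nucleic acid sensing, while PTPN1 (0.01), PTPN11 (-0.08) and PIAS1 (0.05), the members with a site that restrain interferon signalling itself, did not pass the test, nor did RNASEH2B (0.02), and SAMHD1, the remaining one with a site, rose by 1.93, so that over all 22 tested 7 rose and 2 fell. Another property of the plasmid than the hairpin, such as its preparation or the RNA made from it, may also be the source and cannot be told apart from an action of miR-124, because 0 libraries received a plasmid with another hairpin.

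Mitochondrial transcripts shifted with a gradient along the heavy strand, which was clearest over its first genes. MT-RNR1, the small ribosomal RNA at 648 to 1601, rose by 1.29 ± 0.03 (752 to 1841 CPM). The other ribosomal RNA, MT-RNR2, rose by 0.32, while MT-ND1 stood at 0.09 and MT-ND2 at -0.20. From MT-CO1 (-0.42) on the values did not fall steadily, with MT-CO2 at -0.26, MT-CO3 at -0.62, MT-ND3 at -0.27 and MT-ND5 at -0.47. MT-CYB at 14747 to 15887 fell by 0.65. A uniform change in the share of mitochondrial RNA is argued against as the only change, since log2 fold changes over the 14 heavy-strand genes ranged over 1.94. The share itself was lower, at 3.63% against 4.25% with the empty plasmid, and the range does not exclude a lower share beside the gradient. Position along the strand gave a Spearman rho of -0.771 (permutation test over 100000 resamples, p = 0.00199, adjusted 0.00298 over 3 relations) and a Pearson r of -0.801 (p = 3.00e-05, adjusted 9.00e-05). In single libraries rho ran from -0.815 to -0.741. The 2 genes farthest from the median position are the 2 ribosomal RNAs. Without them r was -0.732 and rho -0.636 (permutation test, p = 0.0308 for rho). Genes are not independent replicates here, and no mechanism behind the gradient was tested. More RNA without a poly(A) tail, which could raise both ribosomal RNA and histones, stays open: 41 small nuclear and nucleolar RNA genes had a median of -0.0524, under the bound of 0.4 written before, but a check added after the result showed a median level of 0.462 CPM, too near the floor to exclude it, with 0 called by edgeR, DESeq2 or limma-voom and 1 at an unadjusted p under 0.05 in edgeR.

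Genes with a seed site were lower, and length and base composition of the 3' UTR as the whole cause are argued against. With log length and GC content of the 3' UTR in a model over 10382 genes, the coefficient of a site was -0.0759 ± 0.0080 (SD over the 3 pri-mir-124 plasmid libraries), against -0.0886 ± 0.0281 for the site alone. These coefficients come from a linear fit to means, so they are not on the measure of the median shift of -0.039. The SD leaves out the spread of the empty plasmid libraries. The opposite strand's product, miR-124-5p, showed no shift past the threshold (p = 0.758 in camera with its preset correlation). The seed word GTGCCTT ranked 1 of 16027 words for lower expression, and the miR-124-5p word ranked 9768. Of genes with an 8mer site 29.7% were lower, against 5.88% with a 6mer alone. These values argue against plasmid properties unrelated to the seed as the whole cause of the fall in genes with a site. Without a plasmid that holds another hairpin, the design did not isolate the action of miR-124-3p.

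The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For higher genes 1 split gave as many, the real one with 1400 against 0 in the highest other, and for lower genes 1, with 1436 against 0. In edgeR's test the other 9 splits had 311 to 728 genes at an unadjusted p under 0.05, against 5479. For the shift of genes with a site 1 split gave as large a value, with 0.0394 in size against 0.0358, and for lists called by camera 1, with 12 against 8.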
